A study of Homo sapiens with 15 samples.

How the data were processed

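Gene expression was measured on 15 arrays of the Affymetrix HG-U133 Plus 2.0 type, as named in the probe annotation used here, with 3 arrays for each of 5 cell populations of one lineage. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made by the standard Affymetrix protocol. The deposited values are linear intensity values, 1 per probe set and array. How the authors summarised and scaled the probe intensities is not given in the sources used here. All 15 arrays share the same lowest intensity of 3.84, and their medians lie close together, so that some floor or background model and some scaling had been applied before deposit. The DNA arrays of the same lines that the design text mentions were not analysed here.

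The table held 54613 probe sets. Of these, 41091 carried exactly 1 gene symbol in the probe annotation, 1801 carried several and were not named, and 11721 were not listed there. Entrez identifiers of 41037 probe sets matched the gene table, and 0 symbols needed updating. The table held 0 control probe sets, so the usual ratio of 3' to 5' control signals as a measure of RNA quality could not be formed. Intensities were transformed as log2(intensity + 16), with the scaling between arrays left as deposited. Fold changes are differences on this scale, which understates the change of dim genes. Each of 19775 genes was represented by its probe set with the highest mean over the 15 arrays. A gene was tested if that probe set lay above the 40th percentile of its array on at least 3 arrays, which left 16275 genes. That percentile lay between 5.15 and 5.25 on the log2 scale, and group means under it are close to background.

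A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, so that the 5 groups shared 1 estimate of the spread per gene, and variances were moderated with eBayes without a trend. The p-values, from tests of either direction, were adjusted by the Benjamini-Hochberg method within each of 8 comparisons. A gene was called higher or lower at an adjusted p under 0.05 and a change of at least 2-fold, that is 1 on the log2 scale. A moderated F-test over the same fit counted the genes that differed among the 5 groups. Shifts of 20 gene lists, drawn up from textbook knowledge, and of 23 chromosomes were tested with camera in limma, which compares the genes of a set with all other tested genes. The preset correlation between genes was 0.01, and p-values were adjusted over 160 list tests and 184 chromosome tests; every camera p given for these lists and chromosomes is adjusted. With a correlation estimated from the data in place of the preset one, 19 of 51 list shifts and 0 of 13 chromosome shifts stayed under 0.05. With the 15 arrays regrouped at random, the preset correlation gave 18 to 51 list shifts with a median of 37. Members of a list were also adjusted over the list alone. For display, tested genes were ordered along each chromosome and divided into runs of 50 or more neighbours.

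The 20 lists covered epithelial junction and polarity, basal keratinocyte, luminal breast and mesenchymal genes, estrogen receptor targets, estrogen metabolism and redox, cell cycle, p53 targets and apoptosis, TGF-beta and BMP signalling, interferon response, antigen presentation, NF-kB cytokines, proteases and invasion, WNT and NOTCH, hypoxia and glycolysis, and the unfolded protein response. Markers of haematopoietic, endothelial, and adipocyte and muscle cells stood for other cell types, and the last list was a panel of tumour suppressors and oncogenes. In each comparison the named genes were the 8 with the highest and the 8 with the lowest log2 fold change among called genes whose values did not overlap between the groups, and any member of a list. Examples of a list were its called members with the largest absolute change. Groups, comparisons, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined.

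The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter or a 60th percentile filter on dim probe sets, the mean of all probe sets of a gene, leaving out _x_at probe sets, a type that can cross-hybridise, moderation with a trend and robust, a fit to the 6 arrays compared, array weights, the replicate number as a block, no limit on the fold change, an adjusted p under 0.01, an estimated correlation, fry in place of camera, and leaving out each array in turn. After the data had been seen, cyclic loess normalization, leaving out bcMCF replicate 3 from every comparison, leaving all bcMCF arrays out of the shared fit, and leaving out replicate 1 of both bsMCF and bcMCF were added. The procedure was tested on simulated data with 16275 genes, some of which were changed between caMCF and bsMCF. It recovered 62 of 72 genes changed by 1.5 on the log2 scale, 56 of 58 changed by 2, and 70 of 70 changed by 3, and called 1 gene that had not been changed. The real arrays differed in spread between groups and had correlated genes, so that recovery there may be lower than in the simulation. Figures were drawn with Python 3.11.15.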

Results

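The series followed MCF-10F, a line of immortal, estrogen receptor-negative, non-tumorigenic human breast epithelial cells, through transformation by estradiol. Each of 5 populations was measured on 3 arrays. MCF-10F was the untreated parent, and trMCF was the population transformed by repeated exposure to 70 nM 17-beta-estradiol over 2 weeks. The bsMCF cells were the trMCF cells that had migrated through a Boyden chamber, a porous membrane used to select invasive cells. The bcMCF cells were a clone expanded from bsMCF in culture, and the caMCF lines came from tumours that bsMCF cells had formed in immunodeficient SCID mice. Median probe set intensities ranged from 26.2 to 29.995 over the 15 arrays, and the number of arrays limits the precision. The labels call the 3 arrays of a group biological replicates without naming separate cultures, clones or tumours, so that p-values measure only the spread between these samples. Correlations of log2 values lay between 0.933 and 0.986 within groups and between 0.869 and 0.971 across groups. The median SD of a gene was 0.17 in caMCF, 0.18 in trMCF and 0.19 in MCF-10F, and it was 0.25 in bsMCF and 0.29 in bcMCF. On bcMCF replicate 3, 1252 genes lay over 2-fold from the mean of the other arrays of its group, against at most 732 on any other array. By the moderated F-test of limma, 3612 of 16275 genes differed among the 5 groups.

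**Figure D1:**
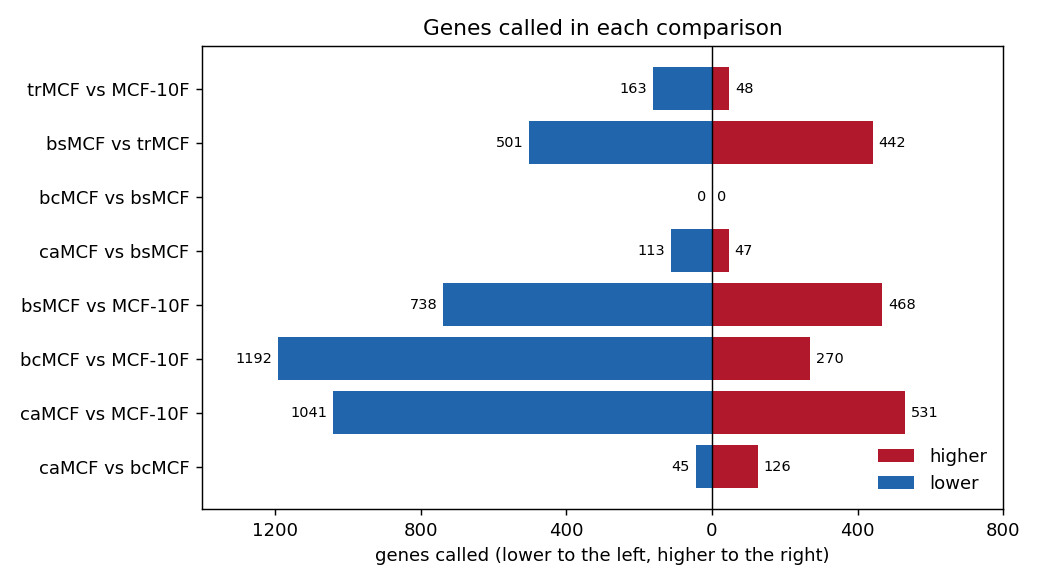
Number of genes called lower (bars to the left, blue) and higher (bars to the right, red) in each of the 8 comparisons, out of 16275 tested, with 3 arrays per group. The comparison of bsMCF with trMCF called 442 genes higher and 501 lower, and that of bcMCF with bsMCF called 0 in either direction.

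The first step compared trMCF, the population transformed by estradiol, with the untreated parent MCF-10F. The labels name no untreated cells kept in culture for the same time, so that estradiol cannot be told apart from time in culture. Fibronectin (FN1), a glycoprotein of the extracellular matrix, fell most, by 4.73 on the log2 scale (SE 0.26, adjusted p = 5.78e-08), from 11.25 ± 0.59 in MCF-10F to 6.52 ± 0.47 in trMCF (mean ± SD, n = 3). The interferon-induced TRIM22 fell by 4.04 (SE 0.19, adjusted p = 1.06e-08) to a level close to background. Also lower were transglutaminase 2 (TGM2) at -3.41, glutamine synthetase (GLUL) at -3.07, the cytochrome c oxidase subunit COX7A1 at -3.001, the proteoglycan SRGN at -2.95 and the cystatin CST6 at -2.80. The genes that rose most were DCN, which encodes the matrix proteoglycan decorin, by 2.28, S100A7 by 2.20 (SE 0.26, adjusted p = 0.000257), CENPV by 2.03, the aldo-keto reductase AKR1B10 by 1.63, MLF1 by 1.54, POLE2 by 1.52, ELOVL3 by 1.47 and MYBL2 by 1.42. Several of these changes depended on the probe set. The 7 probe sets of DCN ranged from -0.02 to 2.28, and their mean at 0.96 was not called. The 7 of FN1 ranged from -5.56 to -0.41, and the 4 of TGM2 from -3.41 to 0.32. The 4 of GLUL ranged from -3.07 to -0.16, and the 3 of SRGN from -2.95 to -0.08. The interferon-induced IFI27 fell by 2.73 with an adjusted p of 0.0437 and an SD of 2.04 within MCF-10F, and its call was lost without any of 5 of the 6 arrays compared, MCF-10F replicate 1 being the exception. Without MCF-10F replicate 2 it was at -1.58. DCN and S100A7 in MCF-10F and SRGN in trMCF were close to background. The call of POLE2 was lost without MCF-10F replicates 2 or 3 or trMCF replicates 1 or 3, and that of ELOVL3 with a pseudocount of 64, at 0.88.

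The cell cycle list shifted up in trMCF. Of 43 measured members, 7 were called higher, 0 lower and 36 were not called (8 higher when adjusted over the list alone), with a median of 0.84 and adjusted camera p = 1.62e-32, and adjusted p = 0.048 with an estimated correlation. Examples were MYBL2 at 1.42, the proliferation marker MKI67 at 1.34 and the mitotic kinase AURKB at 1.33. Among 32 p53 and apoptosis genes, 4 were lower, 0 higher and 28 not called (5 lower when adjusted over the list alone), led by GDF15 at -2.73 and TP53I3 at -2.69, with adjusted camera p = 1.25e-07, and adjusted p = 0.203 with an estimated correlation. The interferon list had 3 of 36 genes lower, 0 higher and 33 not called (7 lower when adjusted over the list alone), with camera p = 2.68e-07 and adjusted p = 0.312 with an estimated correlation, and its median of -0.37 was -0.20 without MCF-10F replicate 2. Of 48 mesenchymal genes, 1 was higher (DCN), 10 were lower and 37 were not called (2 higher and 11 lower when adjusted over the list alone). Beside FN1 they included the fibroblast protease FAP at -2.20, the ectonucleotidase NT5E at -2.16 and N-cadherin (CDH2) at -1.51 (camera p = 3.03e-05, and adjusted p = 0.256 with an estimated correlation). The mesenchymal median of -0.12 was -0.20 without MCF-10F replicate 3 or trMCF replicate 1 and -0.23 without trMCF replicate 3. The epithelial junction list shifted down with 3 of 32 genes lower and 29 not called (3 lower also when adjusted over the list alone; median -0.25, camera p = 6.14e-05, and adjusted p = 0.048 with an estimated correlation), including RAB25 at -1.17. In the basal keratinocyte list the protease KLK7 was lower, at -1.91, and 19 genes were not called (2 lower when adjusted over the list alone; median -0.35, camera p = 3.26e-05, and adjusted p = 0.00644 with an estimated correlation). CDH1, which encodes E-cadherin, and EPCAM were not called. The list of estrogen receptor targets had 0 of 22 genes higher and 1 lower, cyclin D1 (CCND1) at -1.38 (1 also when adjusted over the list alone), with a median of 0.02, a mean of -0.13 and adjusted p = 0.519 by camera. Some of these calls were lost without single arrays, that of CDH2 without MCF-10F replicate 2, CCND1 without MCF-10F replicates 2 or 3, MKI67 without those or trMCF replicate 3, and GDF15 without MCF-10F replicates 2 or 3 or trMCF replicates 1 or 3. Left-out arrays moved CDH2 from -1.76 to -1.19, CCND1 from -1.43 to -1.31, MKI67 from 1.05 to 1.70 and GDF15 from -3.12 to -2.48. ESR1 itself lay between 5.89 and 6.02 in all 5 groups and was called in 0 comparisons.

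In total, 48 genes were higher and 163 lower in trMCF than in MCF-10F. The counts rested on single arrays. They were 114 higher without MCF-10F replicate 1, 21 and 96 without replicate 2, 18 and 85 without replicate 3, 25 higher without trMCF replicate 1, 100 lower without replicate 2, and 24 and 105 without replicate 3.

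The second step, from trMCF to bsMCF, addressed what distinguished the cells that had passed the Boyden chamber from the population they came from. Genes of epithelial cell junctions fell as a group. Of 32 measured members, 27 were called lower, 0 higher and 5 were not called (27 lower also when adjusted over the list alone), with a median of -2.66, adjusted camera p = 6.93e-52 and adjusted p = 1.76e-05 with an estimated correlation. CDH1 fell by 4.69 (SE 0.27, adjusted p = 2.6e-08), from 10.37 ± 0.14 to 5.68 ± 0.81 (n = 3), and also lower were the surface glycoprotein EPCAM at -4.46 (SE 0.32), the transcription factor ELF3 at -4.06, the membrane protease ST14 at -4.06 and the splicing regulator ESRP1 at -3.50. Of 20 luminal genes, 11 were lower, 0 higher and 9 not called (11 lower also when adjusted over the list alone; camera p = 3.45e-08, and adjusted p = 0.0027 with an estimated correlation), led by CD24 at -5.15, LCN2 at -3.80 and ALDH1A3 at -3.41. Of 20 basal keratinocyte genes, 8 were lower, 1 higher and 11 not called (9 lower and 1 higher when adjusted over the list alone; camera p = 9.56e-11, and adjusted p = 0.0004 with an estimated correlation). They included FGFBP1 at -4.51, TRIM29 at -4.47, the desmoglein DSG3 at -4.46 and KLK5 at -4.24. The 3 probe sets of TRIM29 ranged from -4.83 to 0.04. The gene of this list that rose was DST, at 1.23, whose probe sets ranged from -1.32 to 1.37. The retinoid-responsive RARRES1, outside these lists, fell by 4.96.

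Mesenchymal genes moved the other way. Of 48, 18 were called higher, 0 lower and 30 were not called (18 higher also when adjusted over the list alone), with a median of 0.27, a mean of 0.99, adjusted camera p = 4.14e-10 and adjusted p = 0.048 with an estimated correlation. Without bsMCF replicate 1 the median was 0.44. FN1 rose by 5.52 (SE 0.26, adjusted p = 2.99e-09) to 12.04 ± 0.08, the collagen chain COL6A3 by 4.07, NT5E by 4.02, the receptor kinase AXL by 3.25, and vimentin (VIM) by 1.99. FN1 had been at 11.25 ± 0.59 in MCF-10F, so that most of its rise reversed the fall in trMCF. Among transcription factors of this list, FOXC2 rose by 3.18, ZEB1 by 3.06, SNAI2 by 2.67, TWIST1 by 1.87 and ZEB2 by 1.57. The 4 probe sets of ZEB1 ranged from 0.35 to 3.06, the 5 of ZEB2 from 0.09 to 1.57 and the 2 of FOXC2 from 0.53 to 3.18. Across all genes the largest rises were SRGN by 6.18 (SE 0.19, adjusted p = 2.57e-11), FN1, TMEM158 by 5.23, the granulocyte growth factor CSF3 by 5.20, the insulin-like growth factor binding protein IGFBP4 by 5.14, DPYSL3 by 5.10, the pentraxin PTX3 by 4.56 and LAPTM5 by 4.38. All of these but FN1 were close to background in trMCF, as were COL6A3, ZEB1 and ZEB2, and the size of such a rise depends on the pseudocount. The 3 probe sets of SRGN ranged from 0.20 to 6.24, the 3 of DPYSL3 from 0.28 to 5.10 and the 7 of FN1 from 1.20 to 6.41. With a pseudocount of 64 ZEB2 was at 0.77 and not called. In the panel of tumour suppressors and oncogenes, 3 of 25 genes were higher, 0 lower and 22 not called (3 higher also when adjusted over the list alone; adjusted p = 0.803 by camera). They were HRAS, DLC1 at 2.56 and CCND1 at 1.13, whose call was lost without bsMCF replicate 2, at 0.95. HRAS, a small GTPase upstream of the ERK kinases, rose by 3.56 (SE 0.18, adjusted p = 5.5e-09), from 8.05 ± 0.06 to 11.61 ± 0.23 (n = 3), measured by 1 probe set.

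Of 30 hypoxia and glycolysis genes, 8 were higher, 0 lower and 22 not called (8 higher also when adjusted over the list alone), led by the glucose transporter SLC2A3 at 2.76 and the peptide hormone ADM at 1.69, with camera p = 0.0002 and adjusted p = 0.421 with an estimated correlation. Of 43 cell cycle genes, 3 were lower, 0 higher and 40 not called (3 lower also when adjusted over the list alone), among them CCNA2 at -1.62, with camera p = 1.18e-05 and adjusted p = 0.489 with an estimated correlation. Without bsMCF replicate 3 the medians of these lists moved from 0.19 to 0.08 and from -0.49 to -0.28. LAPTM5 was the only called gene of 13 haematopoietic markers, and the pan-leukocyte gene PTPRC lay at 5.03 ± 0.17 in bsMCF and 5.13 ± 0.20 in trMCF. FABP4 at 2.59, not called without bsMCF replicate 3 (2.06), was the only called gene of 10 adipocyte and muscle markers, and 0 of 11 endothelial markers were called. SLC2A3, LAPTM5 and FABP4 were close to background in trMCF. The camera p-values of the haematopoietic, endothelial, and adipocyte and muscle lists were 0.207, 0.35 and 0.272. Altogether 442 genes were higher and 501 lower in bsMCF. With a pseudocount of 64 the counts were 258 and 287, and with the mean of all probe sets 291 genes were higher.

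**Figure D2:**
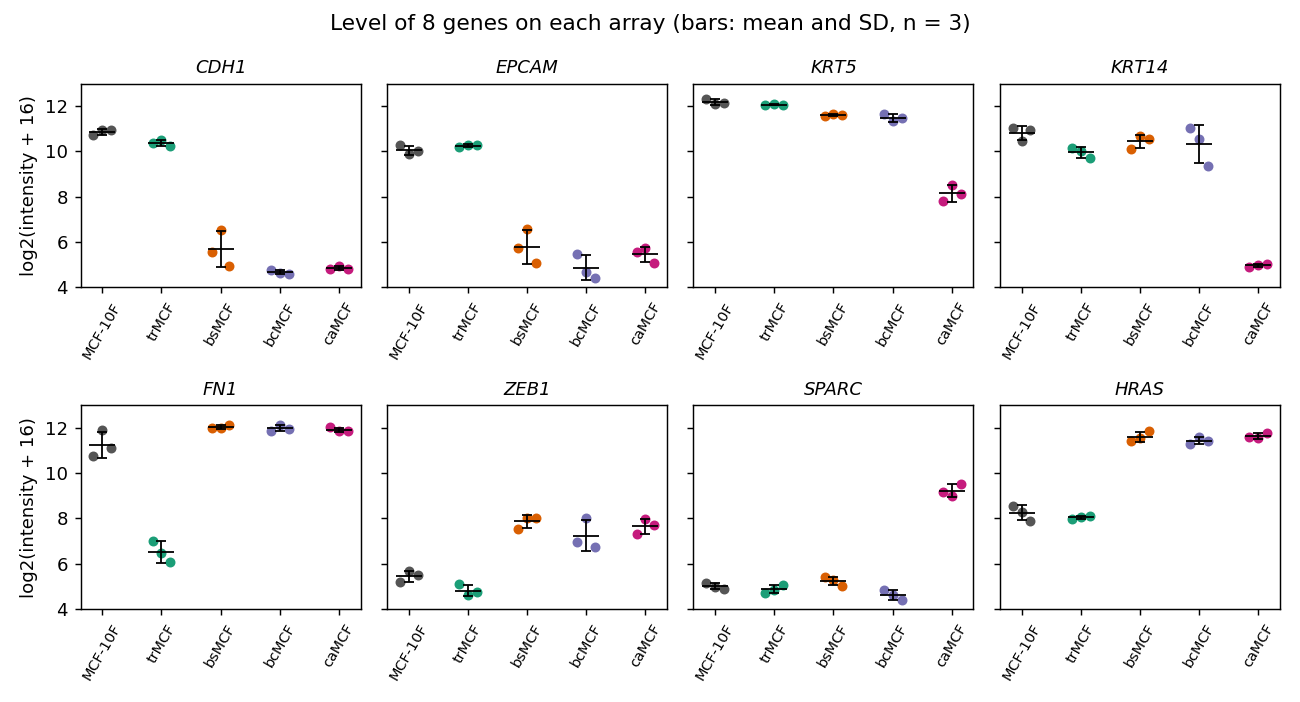
Level of 8 genes on each of the 15 arrays, as log2(intensity + 16), by group. Points are arrays and bars give the mean and SD (n = 3); CDH1 averaged 10.37 in trMCF and 5.68 in bsMCF, HRAS 8.05 and 11.61, while KRT14 averaged 10.44 in bsMCF and 4.96 in caMCF.

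On chromosome 4, 71 of 601 tested genes were lower and 3 higher than in trMCF, the median was -0.27 against -0.01 for all other genes, and 73.0% of its genes lay below 0 against 51.1% elsewhere (adjusted camera p = 1.45e-09, and adjusted p = 0.693 with an estimated correlation). Chromosome 8 had a median of -0.12 (adjusted p = 0.0216, and adjusted p = 0.997 with an estimated correlation; not called without bsMCF replicate 1), with its lowest runs between ZDHHC2 and ANK1, where 3 runs of 50 genes had medians of -0.30, -0.35 and -0.30. Chromosome 1 had a median of 0.08 (adjusted p = 0.0105, and adjusted p = 0.693 with an estimated correlation). In trMCF against MCF-10F, chromosomes 11 and 15 had medians of -0.06 and -0.11 (adjusted p = 0.00724 and 0.00307, and adjusted p = 0.693 and 0.920 with an estimated correlation).

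The third step in culture, from bsMCF to the clone bcMCF, compared the clone with the cells it came from. HK2, a hexokinase of glycolysis, came closest to the threshold among the members of the lists, at -1.08 (SE 0.17, adjusted p = 0.0541). No gene of any list was called, and 3 lists had a camera p under 0.05 with the preset correlation. In the unfolded protein response list 0 of 29 genes were called over all genes and 6 were lower when adjusted over the list alone (median -0.40, camera p = 0.0256, and adjusted p = 0.489 with an estimated correlation). In the hypoxia and glycolysis list 0 of 30 were called and 3 were lower when adjusted over the list alone (median -0.35, camera p = 0.000274, and adjusted p = 0.421 with an estimated correlation). The p53 list had 0 of 32 called, also when adjusted over the list alone (median -0.35, camera p = 0.0316, and adjusted p = 0.56 with an estimated correlation). The unfolded protein response result was lost without bsMCF replicate 3 or bcMCF replicates 1 or 2 (medians from -0.44 to -0.22), that of hypoxia without bcMCF replicate 2 (-0.51 to -0.23, and -0.23 also without bcMCF replicate 1) and that of p53 without bsMCF replicates 2 or 3 or bcMCF replicates 1 or 3 (-0.49 to -0.24). On bcMCF replicate 3 the genes of middle level had a median deviation of -0.53 from the other arrays of its group. Limma called 0 genes higher and 0 lower with a smallest adjusted p of 0.0541, while 2136 genes had an unadjusted p under 0.05. The fit to the 6 arrays alone called 1 higher, the trend and robust fit called 1 lower, the fit without _x_at probe sets called 2 higher and 5 lower, and array weights called 0. The counts depended on single arrays. They were 28 higher and 283 lower without bsMCF replicate 1, 0 and 3 without bsMCF replicate 3, 4 and 15 without bcMCF replicate 1, and 1 and 23 without bcMCF replicate 2, and stayed 0 and 0 without bcMCF replicate 3. Replicate 1 of bsMCF correlated with the bcMCF arrays at a mean of 0.962 and with its own group at 0.950, and replicate 1 of bcMCF with the bsMCF arrays at 0.956 and with its own group at 0.944. Without both of these arrays, a setting chosen after these values had been seen, 77 genes were higher and 816 lower in bcMCF.

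The third step in the mouse, from bsMCF to the tumour-derived caMCF, compared the tumour-derived lines with the cells that had been injected. The keratin genes KRT14 and KRT5 were lower in caMCF. KRT14 fell by 5.48 (SE 0.32, adjusted p = 8.86e-08), from 10.44 ± 0.30 to 4.96 ± 0.05 (n = 3), which is close to background, KRT5 fell by 3.47 (SE 0.17, adjusted p = 1.58e-08) and KRT15 fell by 2.50. Of 20 basal genes, 4 were lower, 0 higher and 16 not called (4 lower also when adjusted over the list alone; median -0.50, camera p = 3.4e-08, and adjusted p = 0.00127 with an estimated correlation). Of 32 junction genes, 5 were lower, 0 higher and 27 not called (6 lower when adjusted over the list alone; median -0.28, and -0.17 without bsMCF replicate 2; camera p = 4.73e-08, and adjusted p = 0.00851 with an estimated correlation). The desmosomal plaque protein DSP was at -3.41, the transcription factor EHF at -2.59 and the desmoglein DSG2 at -2.19, DSP and EHF being close to background in caMCF. The calls of KRT15 and EHF were lost without any one of 5 of the 6 arrays, all but bsMCF replicate 3 for KRT15 (values from -3.41 to -2.00) and all but bsMCF replicate 1 for EHF (-3.01 to -2.34). Among NF-kB cytokine genes, 3 of 31 were lower, 0 higher and 28 not called (7 lower when adjusted over the list alone), with a median of -0.71. Complement C3 was at -3.07 and the chemokine CCL20, not called without any one array but bsMCF replicate 1 (-3.33 to -2.42), at -2.76 (camera p = 2.62e-08, and adjusted p = 0.312 with an estimated correlation).

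SPARC, a matrix-binding glycoprotein, rose most in caMCF (SE 0.18, adjusted p = 8.36e-09), from 5.23 ± 0.19 to 9.23 ± 0.28 (n = 3). SFRP1, a secreted WNT antagonist, rose by 3.03, MIF-AS1 by 2.81, WASIR2 by 2.80, galectin-9 (LGALS9) by 2.64, TCF3 by 2.32, PTPRS by 2.13 and the immunoproteasome subunit PSMB9 by 1.99. The 4 probe sets of SFRP1 ranged from -0.27 to 3.03, the 4 of PTPRS from 0.17 to 2.13 and the 14 of TCF3 from -0.81 to 2.32, and with the mean of all probe sets TCF3 at 0.18 and PTPRS at 0.72 were not called. The call of MIF-AS1 was lost without bsMCF replicates 2 or 3 or caMCF replicates 1 or 2, as was that of TCF3. With a pseudocount of 64 MIF-AS1 at 1.64 and TCF3 at 1.89 were not called, nor was TCF3 with the replicate number as a block. Beside KRT14, KRT5, DSP and C3, the lowest were the carboxylesterase CES1 at -3.10, PKIB at -2.97, PSIP1 at -2.93 and the monoamine oxidase MAOA at -2.79. The 2 probe sets of PKIB ranged from -2.97 to -0.78 and the 4 of PSIP1 from -2.93 to 0.02. MIF-AS1, LGALS9 and PSMB9 in bsMCF, and KRT14, DSP, PKIB and FABP4 in caMCF, were close to background. The call of CES1 was lost without caMCF replicate 1 and that of MAOA without caMCF replicate 2. The mesenchymal list had 2 of 48 genes higher and 4 lower, with 42 not called (3 higher and 7 lower when adjusted over the list alone; adjusted p = 0.168 by camera), SPARC rising and DCN falling by 2.07. In the panel of tumour suppressors and oncogenes, 2 of 25 genes were lower and 23 not called (2 lower also when adjusted over the list alone; adjusted p = 0.09 by camera), MET at -1.05 and MYC at -1.04. The call of MET was lost without bsMCF replicates 2 or 3 or caMCF replicates 1 or 3 (-1.16 to -0.95), and those of MYC and FABP4 without any one array but bsMCF replicate 1 (-1.17 to -0.95 and -3.51 to -2.17). FABP4 was at -2.70, and the camera p-values of the haematopoietic, endothelial, and adipocyte and muscle lists were 0.672, 0.745 and 0.245.

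On chromosome 18 caMCF had 17 of 239 genes lower and 0 higher than bsMCF, and a median of -0.19 against -0.02 elsewhere (adjusted p = 3.17e-10, and adjusted p = 0.395 with an estimated correlation). Its run from ASXL3 to CXXC1 had a median of -0.30, the run from SKA1 to PARD6G had one of -0.37, and the first run had one of -0.01. In all, 47 genes were higher and 113 lower in caMCF. The counts were 196 lower without bsMCF replicate 1, 65 lower without bsMCF replicate 2, 30 and 61 without bsMCF replicate 3, 19 and 48 without caMCF replicate 1, 23 and 55 without caMCF replicate 2, and 74 lower without caMCF replicate 3. Without replicate 1 of both bsMCF and bcMCF 305 genes were lower, and without any bcMCF array in the shared fit 172 were lower.

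**Figure D3:**
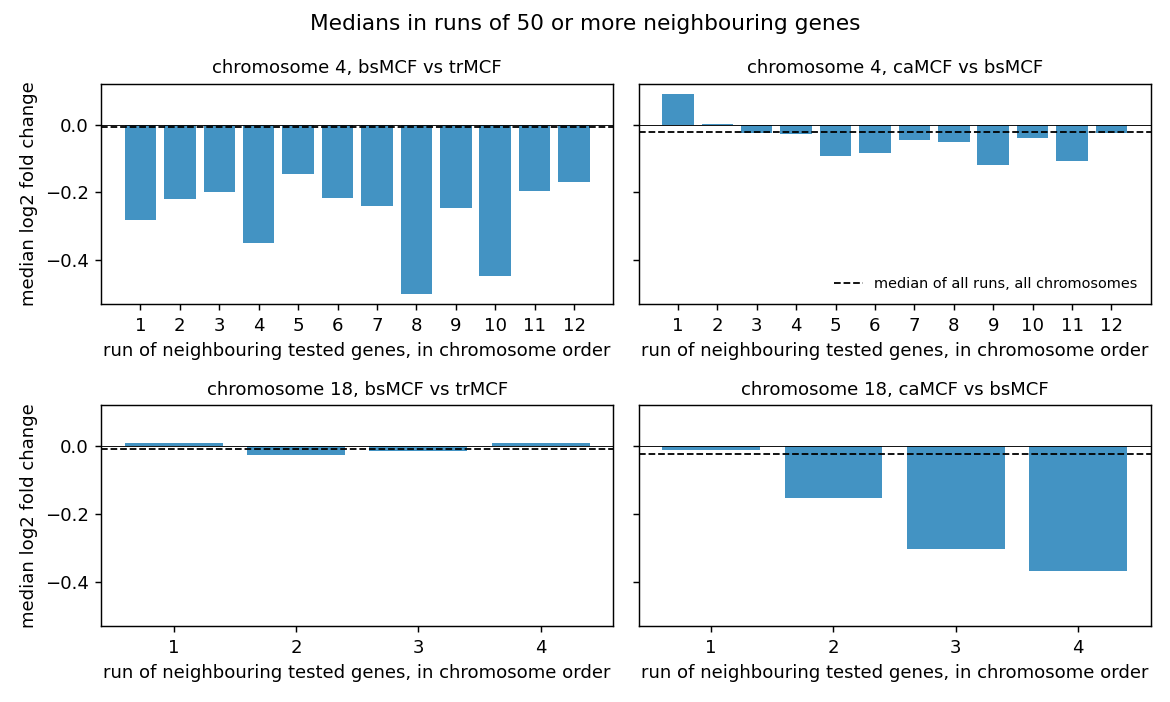
Median log2 fold change in runs of 50 or more neighbouring tested genes along chromosome 4 (top) and chromosome 18 (bottom), for bsMCF against trMCF (left) and caMCF against bsMCF (right), with the median of all runs as a dashed line. All 12 runs of chromosome 4 lie below that line in bsMCF against trMCF, and 3 of the 4 runs of chromosome 18 do so in caMCF against bsMCF.

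A direct comparison of caMCF with bcMCF tested whether the tumour lines and the cultured clone had moved apart after bsMCF. SPARC was higher in caMCF by 4.61 (SE 0.18, adjusted p = 1.01e-09), with 9.23 ± 0.28 against 4.62 ± 0.22 (n = 3), WASIR2 by 3.94, SFRP1 by 3.77, the stathmin STMN3 by 3.27, the secretogranin SCG2 by 2.99, CEP15 by 2.74, LGALS9 by 2.70 and COL6A3 by 2.57. KRT14 was lower at -5.36 (SE 0.32, adjusted p = 1.22e-07), KRT5 at -3.34, C3 at -3.31, PKIB at -2.73, the protease inhibitor SLPI at -2.58, MAOA at -2.43, PSIP1 at -2.41 and DSP at -2.37. SPARC, WASIR2, SFRP1, CEP15 and LGALS9 in bcMCF, and KRT14, PKIB and DSP in caMCF, were close to background, so that the size of their differences depends on the pseudocount. In the fit to the 6 arrays alone SLPI, MAOA, PSIP1 and DSP were not called. The calls of MAOA and DSP were lost without any one of the 3 caMCF arrays, and that of SLPI without caMCF replicate 1, and without bcMCF replicate 1 DSP was at -1.55. The 4 probe sets of SFRP1 ranged from -0.18 to 3.77, the 4 of PSIP1 from -2.45 to 0.19 and the 2 of CEP15 from -0.03 to 2.74. The 2 of SPARC ranged from 1.17 to 4.61, the 2 of STMN3 from 0.41 to 3.27 and the 2 of PKIB from -2.73 to -0.46. The basal list had 2 of 20 genes lower, 0 higher and 18 not called (2 lower also when adjusted over the list alone; median -0.16, camera p = 0.000253, and adjusted p = 0.0132 with an estimated correlation). The junction list had 3 of 32 lower, 1 higher, CLDN4 at 1.502, which was called only with all 6 arrays or without bcMCF replicate 2, and 28 not called (4 lower and 1 higher when adjusted over the list alone; camera p = 0.000414, and adjusted p = 0.0807 with an estimated correlation). The NF-kB list had 2 of 31 lower and 29 not called (3 lower when adjusted over the list alone; camera p = 8.84e-07, and adjusted p = 0.39 with an estimated correlation). The redox list had 1 of 29 lower, AKR1C1 at -1.17, and 28 not called (2 lower when adjusted over the list alone; camera p = 0.00594, and adjusted p = 0.312 with an estimated correlation). Without bcMCF replicate 3 the junction median moved from -0.12 to -0.07 and the basal one to -0.10, and without bcMCF replicate 1 that of NF-kB moved from -0.49 to -0.32. The redox median of -0.11 was -0.07 without bcMCF replicate 1 and -0.19 without replicate 2 or 3. Chromosome 18 had a median of -0.09 against 0.06 elsewhere (adjusted p = 1.28e-05, and adjusted p = 0.693 with an estimated correlation), which was -0.05 without bcMCF replicate 2 and -0.15 without bcMCF replicate 3. In total 126 genes were higher and 45 lower in caMCF. The split was 114 to 80 after quantile normalization and 104 to 94 after cyclic loess. It was 398 and 97 without bcMCF replicate 2, 75 higher without bcMCF replicate 3, 71 and 27 without caMCF replicate 1, 71 and 29 without caMCF replicate 2, and 76 higher without caMCF replicate 3. Without replicate 1 of both bsMCF and bcMCF it was 197 higher.

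Set against the parental line, bsMCF, bcMCF and caMCF each had most junction genes lower. Of 32 members, 27 were lower in bsMCF, 28 in bcMCF and 28 in caMCF, and 0 were higher (the same counts when adjusted over the list alone). The medians were -2.81, -3.12 and -3.34, with camera p = 6.49e-49, 1.47e-41 and 1.82e-46, and adjusted p = 1.76e-05, 2.26e-05 and 1.76e-05 with an estimated correlation. CDH1 was at -5.19, -6.22 and -6.03 in the 3 populations, and its level was 4.66 ± 0.08 in bcMCF and 4.85 ± 0.07 in caMCF (n = 3), both close to background. Of 20 basal genes, 10, 11 and 13 were lower (11, 11 and 13 when adjusted over the list alone), with camera p = 3.19e-16, 2.56e-14 and 6.52e-20, and adjusted p = 8.05e-05, 0.000124 and 3.68e-05 with an estimated correlation. KRT15 was at -3.96, -7.17 and -6.46, with a level of 5.22 in bcMCF. Of 20 luminal genes, 13, 11 and 11 were lower (the same counts when adjusted over the list alone), with camera p = 2.08e-09, 9.86e-08 and 4.04e-08, and adjusted p = 0.00163, 0.00314 and 0.0027 with an estimated correlation. CD24 was at -5.51, -6.68 and -6.69, and RARRES1, TCN1 and S100A14 were also among the lowest genes in at least 1 of the 3 populations. Among the highest genes in all 3 were TMEM158 at 5.42, 4.12 and 5.33, DPYSL3 at 4.97, 4.75 and 5.13, and PTX3 at 4.97, 3.91 and 4.31, all close to background in MCF-10F. The lowest of the 3 probe sets of DPYSL3 were at 0.09, 0.14 and 0.90.

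Mesenchymal genes were split in the same comparisons. Of 48, 13 were higher and 4 lower in bsMCF, 10 and 6 in bcMCF, and 12 and 4 in caMCF (the same counts when adjusted over the list alone). The camera p-values were 0.00311, 0.00672 and 0.0726, and adjusted p = 0.412, 0.421 and 0.56 with an estimated correlation. The median of 0.12 in bsMCF was 0.19, 0.21 and 0.06 without MCF-10F replicates 1, 2 and 3 and 0.21 without bsMCF replicate 2. That of 0.10 in bcMCF was 0.20 without MCF-10F replicate 2 and 0.22 without bcMCF replicate 2. DCN rose by 5.45, 5.70 and 3.38, AXL by 3.38, 3.05 and 3.47, and VIM by 2.06, 2.00 and 2.12, while FAP at -2.33 in bcMCF and -2.72 in caMCF was lower. DCN was close to background in MCF-10F, and its 7 probe sets ranged from 0.06 to 5.45 in bsMCF and from -0.34 to 5.70 in bcMCF. HRAS rose by 3.37, 3.20 and 3.41. Of 32 p53 and apoptosis genes, 11, 14 and 14 were lower and 3, 1 and 0 higher (13, 14 and 14 lower, and 3, 2 and 1 higher, when adjusted over the list alone), led by TP53I3 at -3.42, -3.25 and -3.91, with camera p = 0.00408, 0.000221 and 4.47e-05, and adjusted p = 0.458, 0.408 and 0.387 with an estimated correlation. The cell cycle inhibitor CDKN1A was at -1.98 in bsMCF, where it was not called, -2.66 in bcMCF and -2.26 in caMCF. The bcMCF value rested on replicate 1, without which it was -1.68 and not called, as it was without MCF-10F replicates 2 or 3, and the call in caMCF was lost without any one of the 6 arrays (-2.34 to -2.21). Of 43 cell cycle genes, 5, 3 and 10 were higher and 0 lower (the same counts when adjusted over the list alone), with camera p = 3.07e-05, 4.62e-07 and 5.79e-09, and adjusted p = 0.489, 0.45 and 0.408 with an estimated correlation. In caMCF 11 of 31 NF-kB genes were lower and 1 higher (14 and 1 when adjusted over the list alone), among them S100A8 at -6.06 and CSF3 at 3.50, with camera p = 5.76e-05 and adjusted p = 0.421 with an estimated correlation, and a median of -0.99 that was -1.84 without MCF-10F replicate 1. S100A8 in caMCF and CSF3 in MCF-10F were close to background, and S100A8 had an SD of 2.20 in MCF-10F and probe sets at -6.06 and -2.14.

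These comparisons called 468 genes higher and 738 lower in bsMCF, 270 and 1192 in bcMCF, and 531 and 1041 in caMCF. After quantile normalization the split in bcMCF was 409 to 962, and the median of all genes moved by 0.10 on the log2 scale. With a pseudocount of 64 the counts were 260 and 453, 164 and 665, and 290 and 639. Chromosome 4 had medians of -0.26, -0.37 and -0.34 (adjusted p = 3.44e-10, 2.52e-08 and 1.62e-09, and adjusted p = 0.693 with an estimated correlation in each). Chromosome 5 had medians of 0.15 in bsMCF and 0.13 in caMCF (adjusted p = 0.00241 and 0.00929, and adjusted p = 0.997 with an estimated correlation in both). On chromosome 18 caMCF had 38 of 239 genes lower and 2 higher, and a median of -0.24 (adjusted p = 3.08e-05, and adjusted p = 0.693 with an estimated correlation).

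**Figure D4:**
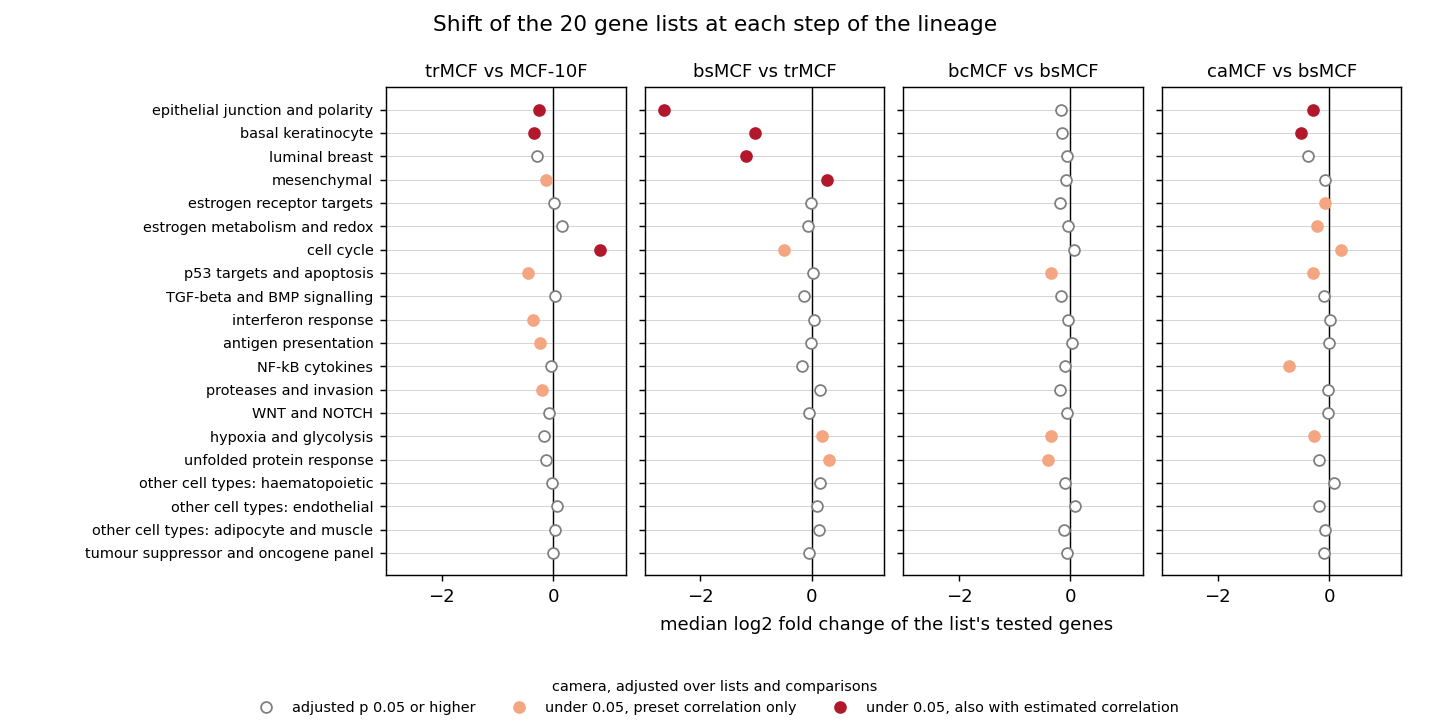
Median log2 fold change of the tested genes of each of the 20 lists in the 4 steps of the lineage, with camera results by colour (open, adjusted p of 0.05 or higher; orange, under 0.05 with the preset correlation only; red, under 0.05 also with an estimated one). The junction list lies at -2.66 in bsMCF against trMCF and the cell cycle list at 0.84 in trMCF against MCF-10F.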

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

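Chosen only after the result had been seen were the tests of a wrong label and of exchanged labels, of a few strongly changed genes and of copy number on chromosome 4, and all 3 tests on HRAS. The other splits of the arrays were chosen before. The test of an intensity-dependent shift and the level-matched sets were chosen before their own results, but they were aimed at patterns already seen in these data.

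The branches out of bsMCF differed by a direct test of caMCF against bcMCF, which called 126 genes higher and 45 lower. Of the named genes, higher were SPARC at 4.61, WASIR2 at 3.94, SFRP1 at 3.77, STMN3 at 3.27, SCG2 at 2.99, CEP15 at 2.74, LGALS9 at 2.70 and COL6A3 at 2.57. Lower were KRT14 at -5.36, KRT5 at -3.34, C3 at -3.31, PKIB at -2.73, SLPI at -2.58, MAOA at -2.43, PSIP1 at -2.41 and DSP at -2.37. SPARC, WASIR2, SFRP1, CEP15 and LGALS9 in bcMCF, and KRT14, PKIB and DSP in caMCF, were close to background, so that the size of these differences depends on the pseudocount. The calls of MAOA and DSP were lost without any one of the 3 caMCF arrays, and that of SLPI without caMCF replicate 1. With a pseudocount of 64 those of SLPI (-1.80) and DSP (-1.34) were lost, and with the mean of all probe sets that of MAOA (-1.93). Without bcMCF replicate 1 DSP was at -1.55. The list medians were -0.12 for epithelial junctions, -0.16 for basal keratinocyte genes, -0.11 for estrogen metabolism and redox and -0.49 for NF-kB cytokines, and the median of chromosome 18 was -0.093. With an estimated correlation the basal list stayed under 0.05 (adjusted p = 0.0132), and junctions (0.0807), redox (0.312), NF-kB (0.39) and chromosome 18 (0.693) did not. Without bcMCF replicate 3 the junction and basal medians were -0.07 and -0.10, and without bcMCF replicate 1 those of redox and NF-kB were -0.07 and -0.32. Redox was -0.19 without bcMCF replicate 2 or 3, and chromosome 18 was -0.05 without bcMCF replicate 2 and -0.15 without bcMCF replicate 3. Among 8058 tested probe sets without exactly 1 gene symbol, outside the gene comparisons, more were lower than higher against MCF-10F. Of those called, 8 of 47 were higher in trMCF, 62 of 195 in bsMCF, 43 of 274 in bcMCF and 108 of 293 in caMCF, and the others were lower. Of the called genes, 77.3%, 61.2%, 81.5% and 66.2% were lower in the same comparisons, so that the excess was not particular to these probe sets.

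The arrays of bsMCF and bcMCF mixed, and bcMCF replicate 3 stood apart with 1252 genes over 2-fold from its group, mostly dimmer at middle levels (median deviation -0.53, against -0.01 for bright genes). After cyclic loess, which removes an intensity-dependent shift, its count was still the highest, with 798 genes against 668 on the next array, bcMCF replicate 1. Both counts are taken within the same mixed group, so that this excess alone does not tell whether an intensity-dependent shift is the whole cause. Such a shift may account for part, since the counts before were 1252 and 732. Another group's array under this label stays open. Its mean correlation with its own group was 0.0127 above that with the nearest other group, but its own group includes bcMCF replicate 1, whose label is itself in doubt. Its deviations from the group mean correlated most with those of bsMCF replicate 1, at 0.513. Deviations cancel out within a group, so that this value is tied to those of bcMCF replicates 1 and 2 with the same array, -0.347 and -0.237. It therefore does not tell whether the label of bcMCF replicate 3 is wrong. The mixing also reached caMCF. Replicate 2 of bcMCF correlated with the caMCF arrays at a mean of 0.968 and with its own group at 0.950. For replicate 2 of bsMCF these means were 0.9535 and 0.9524. An exchange of bsMCF replicate 1 with bcMCF replicate 1 may account for part of the mixing. Each correlated better with the other's group, and exchanging them changed the median SD by -0.0105 in bsMCF and -0.0302 in bcMCF, yet exchanging bsMCF replicate 1 with bcMCF replicate 2 also lowered both, by -0.0191 and -0.0259, and the SDs after the first exchange, 0.24 and 0.26, stayed above those of the other 3 groups. A real spread among the cultures also stays open and was not tested, and the 77 and 816 genes called without both arrays are no independent evidence, since these arrays were picked for how they mixed.

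Chromosome 4 genes had a median of -0.27 over 601 genes in bsMCF against trMCF. A few strongly changed genes as the cause are argued against by the 73.0% of the genes of this chromosome that lay below 0, against 51.1% of all other genes and at most 64.7% on any other chromosome. The expression level of these genes as the cause is argued against by 0 of 10000 level-matched random gene sets with a median as low, the lowest being -0.065 (permutation p = 0.0001, the smallest these sets can give). A lower copy number of chromosome 4 in the selected cells stays open: 12 of 12 runs lay below the median of runs in both bcMCF and caMCF against MCF-10F, but a comparison added after these counts were seen gave 10 of 12 in trMCF, the limit set for this test, so that the count does not tell. The sizes differed. Against MCF-10F the run medians lay between -0.11 and 0.07 in trMCF, between -0.75 and -0.14 in bcMCF and between -0.63 and -0.14 in caMCF. The camera p with an estimated correlation was 0.693 after adjustment, and the DNA arrays that could test the hypothesis were not analysed here.

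HRAS was higher in bsMCF, bcMCF and caMCF than in MCF-10F and trMCF, by 3.56 in bsMCF against trMCF. Scaling between arrays is argued against by the gap between the lowest of the 9 arrays and the highest of the other 6, which was at least 2.75 under 4 scalings, and a gain of the whole region by the 20 nearest tested neighbours, with a median of 0.034, a highest value of 0.57 and 0 called higher. Higher RAS-ERK signalling is a hypothesis in line with 10 ERK-induced genes, a list drawn up after the HRAS level had been seen, in bsMCF against trMCF, where 6 were called higher, including SPRY4 at 3.56 and DUSP6 at 1.96, and DUSP4 at -1.34 was lower (median 1.25, unadjusted camera p of 0.00345 with an estimated correlation and 2.34e-07 with the preset one). The list was lower in trMCF than in MCF-10F (median -0.19, unadjusted camera p of 0.113 and 0.0183 in the same order), which adds to the rise from trMCF, and against MCF-10F the medians were 0.64 in bsMCF, 0.59 in bcMCF and 0.81 in caMCF, with unadjusted camera p-values of 0.0356, 0.130 and 0.0440 with an estimated correlation, so that bcMCF was not under 0.05. A gain of HRAS alone, an introduced copy, cells of another line and cross-hybridisation of its single probe set were not tested.

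Regrouping the arrays gave the following. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in 7 comparisons 1 of the 10, the real one, gave as many genes. The real count and the highest of the others were 211 and 1 for trMCF against MCF-10F, 943 and 0 for bsMCF against trMCF, 160 and 0 for caMCF against bsMCF, 1206 and 1, 1462 and 5, and 1572 and 0 for bsMCF, bcMCF and caMCF against MCF-10F, and 171 and 1 for caMCF against bcMCF. For bcMCF against bsMCF the real count was 0, all 10 splits gave as many, and the highest other was 342, for the split that exchanges the 2 replicates 1, which points to a structure of the samples. The real grouping was also 1 of the 100 splits of the 15 arrays. Only 1 split, the real one, gave as many genes differing among the groups (3612, highest other 2754), so that chance is an unlikely source of this count. For list shifts 2 of 100 gave as many, the real split and 1 random one (51, highest other 51). Chance is thus unlikely for the number as a whole but not excluded. The other splits gave 18 to 51 list shifts with a median of 37. They mix arrays of populations that differ, so that they can carry real shifts and give no rate of false calls. With an estimated correlation only 19 of the 51 list shifts stayed under 0.05, so that a single list shift called with the preset correlation alone is weak evidence. For the chromosome shifts 13 of 100 gave as many (13, highest other 18, median 6), so that chance is not excluded for their number. The limit of mixed populations holds for these splits too.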

How the results depend on the processing

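Cyclic loess, both settings that leave bcMCF arrays out of comparisons without them, and leaving out replicate 1 of both bsMCF and bcMCF were chosen after the data had been seen, and the other settings before. Of 16 named genes per comparison, all kept their calls under every setting in bsMCF against trMCF and in the 3 comparisons with MCF-10F that followed it, 12 did so in trMCF against MCF-10F, 11 in caMCF against bsMCF and 12 in caMCF against bcMCF. Over 725 named or listed gene values, calls were lost with the mean of all probe sets (163 of 724), a pseudocount of 64 (147) and an adjusted p under 0.01 (122). Leaving out single arrays also ended calls, such as 42 of 247 without caMCF replicate 1, 30 of 177 without trMCF replicate 3 and 85 of 527 without MCF-10F replicate 3. Dim genes limit these results, since a probe set near the floor of its array has little signal over background and its fold change depends on the pseudocount. The counts below are higher, then lower, and except where stated the cause of a difference was not tested.

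A pseudocount of 64, which by construction shrinks changes of dim genes, gave 21 and 102 for trMCF against MCF-10F, 258 and 287 for bsMCF against trMCF, 24 and 60 for caMCF against bsMCF, 260 and 453 for bsMCF, 164 and 665 for bcMCF and 290 and 639 for caMCF against MCF-10F, and 61 and 24 for caMCF against bcMCF. Without a fold limit, which by construction admits smaller changes, they were 106 and 254, 828 and 880, 74 higher, 1028 and 1277, 822 and 2102, 1343 and 1792, and 190 higher, in the same order. At an adjusted p under 0.01 they were 20 and 86 for trMCF against MCF-10F, 25 and 53 for caMCF against bsMCF and 66 and 27 for caMCF against bcMCF, with 2113 genes differing among the groups. The mean of all probe sets gave 291 higher for bsMCF against trMCF, 60 lower for caMCF against bsMCF, 298 and 171 higher for bsMCF and bcMCF against MCF-10F and 26 lower for caMCF against bcMCF. Quantile normalization gave 409 higher for bcMCF against MCF-10F and 80 lower for caMCF against bcMCF, and cyclic loess gave 94 lower for the latter. Array weights gave 110 higher for trMCF against MCF-10F and 170 lower for caMCF against bsMCF. The fit to 6 arrays gave 73 and 27 for caMCF against bcMCF. For bcMCF against bsMCF, that fit gave 1 higher, trend and robust 1 lower, and leaving out _x_at probe sets 2 and 5. Without bcMCF in the shared fit, caMCF against bsMCF had 172 lower. Without replicate 1 of both bsMCF and bcMCF, bcMCF against bsMCF had 77 and 816, caMCF against bsMCF 305 lower and caMCF against bcMCF 197 higher. With an estimated correlation, which by construction widens the null of correlated sets, 19 list shifts and 0 chromosome shifts remained. With fry, which compares no list with other genes, 40 of 51 list shifts were called and 11 were not. These were the cell cycle in bsMCF against trMCF and MCF-10F, bcMCF against MCF-10F and caMCF against bsMCF, p53 in bcMCF and caMCF against bsMCF, the unfolded protein response in bsMCF against trMCF and bcMCF against bsMCF, antigen presentation in trMCF, and redox and NF-kB in caMCF against bcMCF. The steroid sulfatase gene STS in bcMCF against MCF-10F turned from -1.18 to 0.24 after quantile normalization, because another of its 4 probe sets became the brightest.

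Leaving out 1 array at a time moved the counts as follows, from lowest to highest. For trMCF against MCF-10F 18 to 114 were higher and 85 to 206 lower, for bsMCF against trMCF 354 to 611 and 411 to 527, for bcMCF against bsMCF 0 to 28 and 0 to 283, and for caMCF against bsMCF 19 to 52 and 48 to 196. Against MCF-10F, 398 to 589 were higher and 648 to 779 lower in bsMCF, 246 to 328 and 876 to 1488 in bcMCF, and 461 to 642 and 930 to 1056 in caMCF, and for caMCF against bcMCF 71 to 398 and 27 to 97. Genes differing among the groups numbered 2767 to 4180, list shifts 47 to 57 and chromosome shifts 12 to 14. The extremes came without bsMCF replicate 1 for bcMCF against bsMCF (28 and 283), without MCF-10F replicates 3 (18 and 85) and 1 (114 and 206) for trMCF against MCF-10F, without bcMCF replicate 2 for caMCF against bcMCF (398 and 97), and without caMCF replicate 1 (19 and 48) and bsMCF replicate 1 (196 lower) for caMCF against bsMCF.

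The replicate number did not pair the arrays as a whole. Of 30 same-numbered pairs, 6 had deviations that correlated over 0.1, as did 13 of 60 pairs with different numbers, the median correlation was 0.003 in both, and 5 of 15 arrays correlated best with their own number. The arrays numbered 2 of bsMCF, bcMCF and caMCF, however, all correlated with each other, at 0.332 for bsMCF with bcMCF, 0.247 for bsMCF with caMCF and 0.299 for bcMCF with caMCF, and whether they shared a day or a culture is not given in the sources used here. The highest correlation of any pair, 0.513, was between different numbers, bsMCF replicate 1 and bcMCF replicate 3. The replicates 1 of bsMCF and bcMCF were at -0.347. With the replicate number as a block, bcMCF against bsMCF had 1 gene lower, 14 of 725 gene calls and 2 of 64 set results were lost, the latter the interferon list in bcMCF and caMCF against MCF-10F, and no other count moved by over 1.5 times.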

Other observations

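The comparisons here used lists and genes fixed before the data were seen, and CDKN2A and MTAP were singled out afterwards. Some interferon genes were lower in the later lines than in MCF-10F, and most were not called. Of 36, 7 were lower in bsMCF, 9 in bcMCF and 7 in caMCF, and 1 was higher in each (7, 10 and 7 lower and 1 higher when adjusted over the list alone), with camera p = 0.00289, 0.0419 and 0.0309, and adjusted p = 0.489, 0.63 and 0.618 with an estimated correlation. TRIM22 was at -4.09, -4.05 and -4.03 and IFI27 at -4.00, -4.11 and -4.15, while the guanylate-binding protein GBP1 was the gene that rose, at 2.05, 1.57 and 1.44. TRIM22 and IFI27 were close to background in all 3 lines. The call of GBP1 was lost in bcMCF without MCF-10F replicates 1 or 3 or bcMCF replicate 2 (1.21 to 1.90), and in caMCF without any one array but MCF-10F replicate 2 (1.20 to 1.77). The interferon list result was lost in each line without MCF-10F replicate 2, in bcMCF also without bcMCF replicate 2 and in caMCF without caMCF replicate 3. With the replicate number as a block it was lost in bcMCF and caMCF. Its medians without MCF-10F replicate 1 and without MCF-10F replicate 2 were -0.40 and -0.05 in bsMCF, -0.42 and -0.11 in bcMCF and -0.35 and 0.01 in caMCF, and in bsMCF -0.31 without MCF-10F replicate 3 and -0.28 without bsMCF replicate 2. In the TGF-beta and BMP list the ligands went opposite ways against MCF-10F, TGFB2 at -2.30, -2.80 and -2.70 and TGFB1 at 2.24, 2.13 and 1.99, and the list had no adjusted camera p under 0.05 in any of the 8 comparisons. The same held for the WNT and NOTCH list, in which NOTCH3 at -2.60 and JAG1 at -1.57 were called in trMCF against MCF-10F with all arrays or without MCF-10F replicate 1, and not without any other array (-2.98 to -2.31 and -1.84 to -1.38). In that comparison proteases and invasion genes had 3 of 30 lower (5 lower and 2 higher when adjusted over the list alone; camera p = 0.00857, and adjusted p = 0.397 with an estimated correlation), led by MMP7 at -2.04, close to background in trMCF, and 0 of 18 antigen presentation genes were called, also when adjusted over the list alone (camera p = 0.0307, and adjusted p = 0.458 with an estimated correlation). The protease result was lost without MCF-10F replicate 2 (medians from -0.26 to -0.14), and that of antigen presentation without it or trMCF replicates 2 or 3 (-0.29 to -0.16).

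In estrogen metabolism and redox, AKR1B10 rose by 1.63 in trMCF and then fell by 2.34 in bsMCF, and in caMCF against bsMCF 1 of 29 genes was lower, AKR1C1 at -1.25 (2 lower when adjusted over the list alone; camera p = 0.0164, and adjusted p = 0.39 with an estimated correlation). In the same comparison estrogen receptor targets had 1 of 22 lower, SLC39A6 at -1.01 (3 lower when adjusted over the list alone; camera p = 0.0465, and adjusted p = 0.176 with an estimated correlation). Cell cycle genes had a median of 0.21 with 0 of 43 called (camera p = 5.42e-05, and adjusted p = 0.5 with an estimated correlation), p53 genes -0.30 with 0 of 32 called (1 lower when adjusted over the list alone; camera p = 0.000624, and adjusted p = 0.421 with an estimated correlation) and hypoxia genes -0.27 with 0 of 30 called (2 lower when adjusted over the list alone; camera p = 3.87e-05, and adjusted p = 0.408 with an estimated correlation). Of 29 unfolded protein response genes, 1 was higher in bsMCF than in trMCF and 28 were not called, EDEM1 at 1.07 being lost without any one array but bsMCF replicate 1, with values from 0.90 to 1.41 (1 higher also when adjusted over the list alone; camera p = 0.0115, and adjusted p = 0.458 with an estimated correlation). This list result and that of the cell cycle in caMCF were lost without bsMCF replicate 3 (medians from 0.15 to 0.45 and 0.11 to 0.28), and that of estrogen metabolism without bsMCF replicate 1 (-0.27 to -0.10, and -0.11 and -0.13 without caMCF replicates 1 and 2). The cell cycle median was 0.13 without caMCF replicate 2, the p53 median -0.46 without bsMCF replicate 1 and the hypoxia median -0.11 without bsMCF replicate 3. That of the estrogen receptor targets was lost without bsMCF replicates 2 or 3 or caMCF replicates 2 or 3 (medians from -0.22 to -0.06, with -0.22 and -0.15 without bsMCF replicates 1 and 3 and -0.11 without caMCF replicate 1), and the call of SLC39A6 without bsMCF replicate 2 or caMCF replicates 1 or 3 (-1.21 to -0.85). The haematopoietic, endothelial, and adipocyte and muscle lists had no adjusted camera p under 0.05 in any of the 8 comparisons. CDKN2A lay between 5.79 and 6.28 and MTAP between 5.73 and 5.93 in all 5 groups, and neither was called in any comparison.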
